A study of Drosophila melanogaster with 15 samples.

How the data were processed

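Gene counts from 15 RNA sequencing libraries of Drosophila melanogaster testis cells were analysed, 3 libraries in each of 5 groups (WT, Chinmo, Upd, Ci and the label chinmo RNAi). Per the labels, each sample came from 50 to 100 flies and 100 to 200 testes, cells with tj-Gal4 driven GFP were sorted, and libraries of polyadenylated RNA were sequenced paired-end with 50 cycles. The labels give an age of 10 days after eclosion for every group except chinmo RNAi, whose flies were 2 or 3 days old. They do not say whether the libraries of a group came from separate cultures or on which day they were made, so no batch could be formed.

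The authors named bcl2fastq, STAR, Picard, HTSeq and DESeq2 and the genome builds dm6 and BDGP6. Versions, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited counts were whole numbers per gene and library, with 5 summary lines for reads assigned to no gene. The deposited signal held the same counts divided by 1 size factor per library, which was checked by dividing both (largest gap 0.023 in the unit of that table). All results rest on the counts, and the signal served to read the authors' size factors for 1 alternative scaling. Of 17408 genes, 12903 carried a symbol of the BDGP6.54 annotation, 4329 matched it by 1 synonym and 176 matched nothing. Symbols were kept as listed, and 19 members of the gene lists were found by an alias.

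Genes were kept where edgeR's filterByExpr found enough counts for the group size, which left 10056. Libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group (edgeR 4.0.16, glmQLFit with robust estimation, R 4.3.3) was fitted to all 15 libraries at once and gave a common dispersion of 0.427, a biological coefficient of variation of 65.3%. Each gene was tested with the two-sided quasi-likelihood F test and adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Chinmo, Upd, Ci and chinmo RNAi were each compared with WT, and Chinmo with Upd, Ci and chinmo RNAi as well as Upd with Ci. Levels are CPM after TMM scaling, as mean and SD of 3 libraries. Changes are log2 changes fitted by edgeR with the standard error from the F statistic.

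Before the data were examined, 26 gene lists were fixed for pathways, cell types and complexes of the testis, and 24 had at least 3 measured members and were tested. Camera (limma 3.58.1) compared each list with the other genes at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data, adjusted over the lists of 1 comparison. Fry was the second list test, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Members past the threshold were counted after adjustment over all genes and adjusted over the list alone. The rule for the genes to name was fixed at the same time. It took the genes of the manipulations (chinmo, ci, upd1, Dcr-2 and tj) with the readouts ptc, Socs36E, zfh1, eya, dsx, tra and Yp1. To these it added the 6 widest rises and the 6 widest falls of each comparison with WT, among genes past the threshold with a mean of at least 10 CPM, a name beyond a number and groups that did not overlap. The third part was up to 4 members of each list with the smallest adjusted p, and the fourth was the genes shared by 3 comparisons. A gene without counts in a group was given a limit from 3 counts over that group, and for genes with 0 to 3 counts in a group levels are given and no fold.

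Overlaps between comparisons were set beside the number that independent lists give and beside 40 simulations in which unchanged groups were compared with the same WT libraries, since all comparisons with WT share them.

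The pipeline was tested on simulated data with 3 libraries per group. A change of 2-fold was recovered for 0% of 98 to 100 changed genes in each simulation. A change of 8-fold was recovered for 41.4% (Chinmo), 35.7% (Upd), 25% (Ci) and 33% (chinmo RNAi). False calls made up 12.8%, 2.78%, 7.41% and 0% of all calls. A shifted list of 30 genes was found each time, and camera called 0 of 20 unshifted lists. Whether the 0 holds in real data was not tested. Counts assigned to genes ran from 1143049 in Chinmo 3 to 2943120 in Ci 2. In these simulations most changes of 8-fold or less escaped the single-gene test, and a gene that did not pass is not shown to be unchanged.

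Alternatives planned beforehand were scaling by size factors (RLE) or the upper quartile, no filter on low counts, a stricter filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a germline score as a covariate, a fit of only the 2 groups compared, leaving out each library in turn and, for the list tests, leaving out members held by more than 1 list. The germline score of a library was the mean log2 CPM of the 2 germline lists. Added after the data were seen were the removal of 119 ribosomal RNA genes, a fit without Chinmo 3, sample quality weights in limma-voom and the authors' size factors. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Transcript isoforms, sequence variants and the raw reads were not analysed here.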

Results

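Transcripts were counted in somatic cells sorted by green fluorescence from adult Drosophila melanogaster testes. The fluorescence came from a nuclear GFP under tj-Gal4, a driver that follows the transcription factor gene traffic jam (tj) and is active in the cyst lineage. That lineage starts with the cyst stem cells (CySCs) next to the hub, a cluster of niche cells at the testis tip, and yields the cyst cells that enclose the developing germ line. There were 15 libraries in 5 groups of 3. Control libraries (WT) carried the driver and the GFP. Upd libraries also expressed the ligand Unpaired, which activates JAK/STAT signalling. Ci libraries expressed activated forms of Cubitus interruptus, the transcription factor of the Hedgehog pathway. Chinmo libraries expressed the zinc-finger protein Chinmo, with tub-Gal80TS in the genotype, which WT lacked. The last group carried a hairpin against chinmo together with UAS-dcr2, and its flies were 2 or 3 days old where those of the other groups were 10 days old, so age and dcr2 coincide with that label. Each sample pooled 50 to 100 flies, or 100 to 200 testes. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

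The count table held 17408 genes. Counts assigned to genes were 1949497, 2331362 and 1966444 in WT 1 to 3, 1569692, 1740043 and 1143049 in Chinmo 1 to 3, and 2102093, 2238014 and 2443475 in Upd 1 to 3. They were 2087894, 2943120 and 2123547 in Ci 1 to 3, and 1666727, 1886046 and 2197465 in the 3 libraries labelled chinmo RNAi. At least 1 count was seen for 11174 to 11361 genes in WT and for 11063 to 11812 in Upd. The library Chinmo 3 stood apart with 4983 genes, against 9355 and 10080 in Chinmo 1 and Chinmo 2. Ribosomal RNA genes took 32.3% of its counts and 12.8% to 24.2% in the other 14 libraries. Chinmo RNAi 2 had 8109 genes, against 10324 and 10846 in the other libraries of that label. Mitochondrially encoded genes held 3.15 ± 0.298% of counts in the libraries labelled chinmo RNAi and 6.11 ± 1.11% in WT (SD, n = 3). Levels are given in CPM (counts scaled to a common library total, after TMM). For a gene without a count in a group the limit is 3 counts over that group, which covers counting error only.

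**Figure D1:**
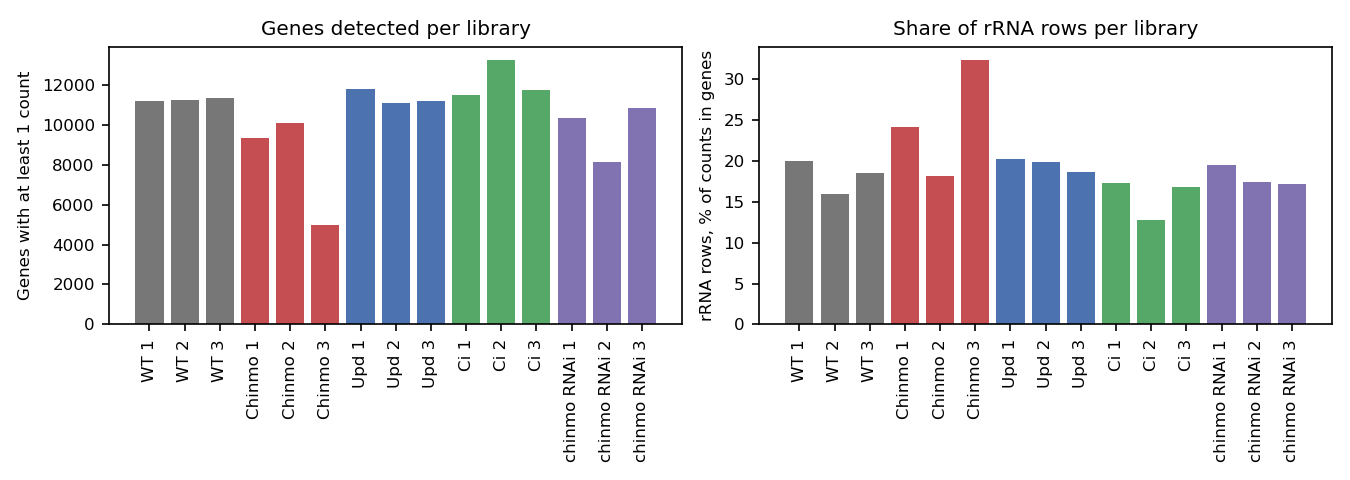
Number of genes with at least 1 count and percent of gene counts in ribosomal RNA genes for each of the 15 libraries, 1 bar per library. Chinmo 3 has 4983 genes and 32.3% ribosomal RNA, against 8109 to 13229 genes and 12.8% to 24.2% in the other 14.

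The genes behind the transgenes were compared first. chinmo, upd1 and ci were raised by design and are list members. chinmo (2L, 1651258 to 1704682, plus strand, BDGP6.54 annotation) stood at 71.9 ± 2.87 CPM in WT and at 418 ± 331 CPM in Chinmo (SD, n = 3), with 100.1, 392 and 761 CPM in the 3 Chinmo libraries. The log2 change was 2.53 ± 0.54 (SE, edgeR adjusted p = 0.027). Without Chinmo 3 it was 1.51 (edgeR adjusted p = 0.0918), and the edgeR adjusted p was 0.0921, 0.165 and 0.137 without WT 1, WT 2 and WT 3. In the libraries labelled chinmo RNAi chinmo stood at 117 ± 48.4 CPM (147, 143 and 61.4 CPM), a log2 change of 0.70 ± 0.51 (edgeR adjusted p = 0.437), with -0.27 once a germline score was in the model and 0.39 to 1.01 in the other alternatives. The targeted transcript was therefore not measured as reduced, and every direction given for these libraries carries that limit. upd1 (X, 18305354 to 18309291, minus strand) rose from 6.78 ± 4.64 to 195.5 ± 16.7 CPM in Upd, by 4.84 ± 0.96 on the log2 scale (edgeR adjusted p = 0.00045). ci (4, 47710 to 57041, minus strand) rose from 27.6 ± 7.98 to 329 ± 164 CPM in Ci, by 3.57 ± 0.54 (edgeR adjusted p = 0.0087). That call was lost without WT 1, WT 2, WT 3 or Ci 1 (edgeR adjusted p = 0.101, 0.132, 0.294 and 0.195). The driver's gene tj (2L, 19464267 to 19467758, plus strand) stood at 6.34 ± 9.20 CPM in WT (16.9, 1.59 and 0.475 CPM), 222 ± 23.2 CPM in Upd and 46.9 ± 13.7 CPM in Ci. Dcr-2 (2R, 17574979 to 17581525, minus strand) stood at 262 ± 74.0 CPM in WT and 427.5 ± 98.8 CPM in the libraries labelled chinmo RNAi, a log2 change of 0.71 ± 0.43 (edgeR adjusted p = 0.341).

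**Figure D2:**
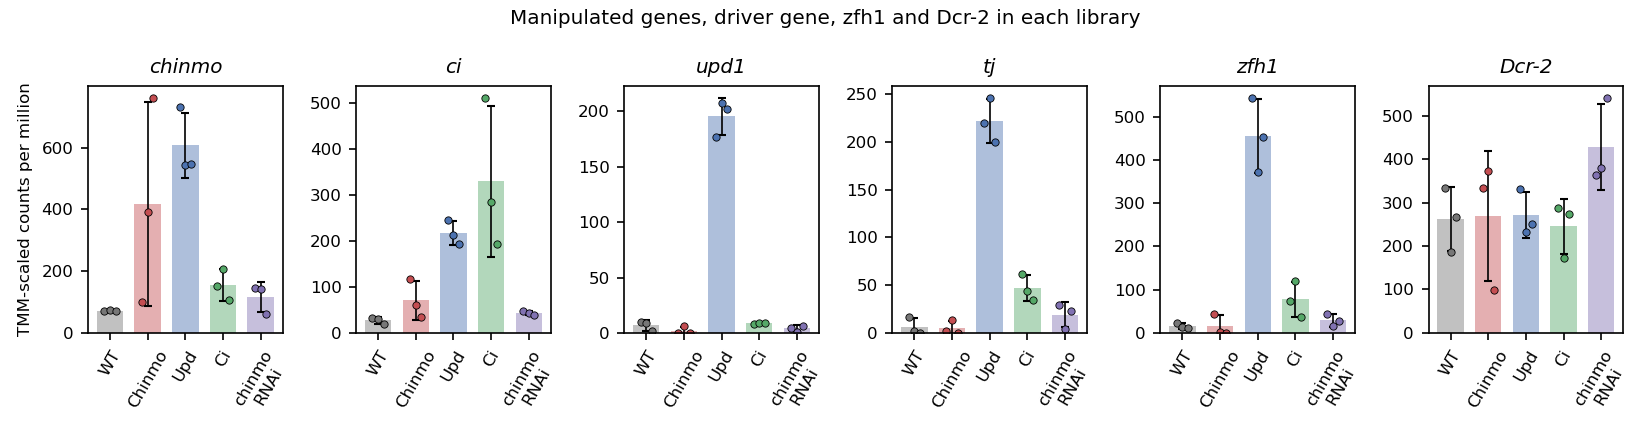
Level of chinmo, ci, upd1, tj, zfh1 and Dcr-2 (CPM after TMM scaling) in the 5 groups, with the 3 libraries of a group as points, their mean as a bar and the SD as error bar. chinmo lies at 117 CPM in the libraries labelled chinmo RNAi against 71.9 CPM in WT, and upd1 at 195.5 CPM in Upd against 6.78 CPM.

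The comparison of Upd with WT asked what ligand-driven JAK/STAT signalling changes in these cells. zfh1, a repressor that maintains CySCs, stood at 456 ± 85.6 CPM in Upd and 15.9 ± 6.78 CPM in WT (SD, n = 3), a log2 change of 4.84 ± 0.90 (SE, edgeR adjusted p = 0.00023). eya, a cofactor of cyst cell differentiation, fell from 267 ± 66.6 to 36.1 ± 25.6 CPM (-2.88 ± 0.57, edgeR adjusted p = 0.00043). Of 15 cyst stem cell factors 10 rose, and 10 adjusted over the list alone (camera adjusted p = 2.7e-06; adjusted p = 0.198 with an estimated correlation). Among them were CadN, a cadherin (441 against 13.5 CPM, 5.03 ± 0.76), Wnt4 (346 against 8.32 CPM, 5.38 ± 0.92), tj (5.14 ± 1.08) and chinmo (607 ± 107 CPM, 3.08 ± 0.55). Of 11 differentiating cyst cell markers 5 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.141). They were eya, the aldo-keto reductase gene Akr1B (listed as CG6084, 209 against 2351 CPM), geko (-4.64 ± 0.83), Nep4 (-4.94 ± 1.05) and Nep5, the last chosen after its values were seen. The log2 change of tj was 7.57 without WT 1, and those of eya and Nep4 were -3.54 and -5.67 without Upd 1.

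Pathway genes moved both ways in Upd. In the JAK/STAT list 5 of 15 rose and 2 fell, as many adjusted over the list alone (camera adjusted p = 0.0512, and 0.0449 without Upd 2). upd1, chinmo, zfh1, the feedback inhibitor Socs36E (157 against 25.9 CPM, 2.59 ± 0.64) and the phosphatase gene Ptp61F rose, while vir-1 and Tep2 fell, and Ptp61F and Tep2 were chosen after their values were seen. In the Hedgehog list 6 of 16 rose and 2 fell, as many adjusted over the list alone (camera adjusted p = 0.141). ci reached 218 ± 25.9 CPM (2.97 ± 0.53), while the ligand genes hh (-5.09 ± 0.90) and dpp (-6.22 ± 0.77, with 6, 3 and 0 counts in Upd 1, 2 and 3) fell. ptc, the Hedgehog receptor and target, stood at 39.1 against 7.55 CPM (2.36 ± 0.91, edgeR adjusted p = 0.048), with adjusted p from 0.0829 to 0.154 when WT 1, WT 2, WT 3, Upd 1, Upd 2 or Upd 3 was left out. Of 8 hub markers upd1, CadN and magu rose and hh, dpp and Fas3 fell, also adjusted over the list alone (camera adjusted p = 0.472). Of 19 EGFR and MAPK genes 8 rose, and adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 0.0011; adjusted p = 0.198 with an estimated correlation), with the repressor gene aop at 364 against 50.7 CPM. Of 12 BMP genes brk and magu rose and dpp and Dad fell, also adjusted over the list alone (camera adjusted p = 0.162). Of 14 JNK and cell death genes puc and hid rose and CG10176 and rpr fell, also adjusted over the list alone (camera adjusted p = 0.181). Calls were lost for hid without WT 3 (edgeR adjusted p = 0.0723), Fas3 without WT 2 or Upd 2 (0.0642 and 0.0502), rpr without WT 2, Upd 1, Upd 2 or Upd 3 (0.0518 to 0.0841) and CG10176 without WT 2, Upd 1, Upd 2 or Upd 3 (0.0504 to 0.098).

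vas, an RNA helicase gene of the early germ line, stood at 383 ± 29.6 CPM in Upd against 8.57 ± 8.62 CPM in WT (SD, n = 3), a log2 change of 5.49 ± 0.92 (SE, edgeR adjusted p = 8.0e-05). Mst77F, a chromatin protein of maturing sperm, fell from 919 ± 280 to 12.8 ± 6.94 CPM (-6.17 ± 0.47, edgeR adjusted p = 3.4e-09). Of 16 early germline markers 14 rose, and 14 adjusted over the list alone (camera adjusted p = 2.1e-08; adjusted p = 0.0754 with an estimated correlation). Examples are aub (268 against 7.45 CPM), qin (248 against 9.80 CPM) and ovo (107 against 0.595 CPM), and the differentiation gene bam lay at 24.4 ± 4.82 CPM with 2 counts over the WT libraries. Of 40 spermatocyte and spermatid markers 26 fell, and 26 adjusted over the list alone (camera adjusted p = 4.1e-12; adjusted p = 0.198 with an estimated correlation). Mst84Db fell from 1394 to 12.7 CPM, and as it lies in a cluster of similar genes on 3R, the split of reads between them is uncertain. The log2 change of vas was 6.64 without WT 1. That of aub went from 5.17 to 6.43 without WT 3 and that of Mst84Db from -6.78 to -7.57 without Upd 1. ProtA, a protamine gene with a near copy, had no count in Upd, which allows up to 0.350 CPM from 3 counts over the group, and lay at 35.4, 178 and 77.4 CPM in WT 1, 2 and 3.

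PCNA, the sliding clamp of DNA replication, went from 28.4 ± 4.15 CPM in WT to 272 ± 7.03 CPM in Upd (log2 change 3.26 ± 0.79) and Top2 from 63.2 to 524 CPM (3.05 ± 0.66). Of 41 cell cycle genes 19 rose, and 21 adjusted over the list alone (camera adjusted p = 1.8e-08; adjusted p = 0.198 with an estimated correlation). Of 87 ribosomal protein genes 72 rose and 2 fell, and 77 and 2 adjusted over the list alone (camera adjusted p = 1.3e-16; adjusted p = 0.299 with an estimated correlation). Early germline markers rose beside these lists, 14 of 16 with a median of 4.54 and vas at 383 CPM against 8.57 CPM in WT. RpL15 reached 2149 ± 88.4 CPM from 420.5 ± 90.5 CPM (2.35 ± 0.34). RpL10Aa and RpS28a, chosen after their values were seen, were the 2 that fell, and size-factor and upper-quartile scaling gave 73 and 74 higher with 1 lower. Of 83 oxidative phosphorylation genes 19 fell, and 18 adjusted over the list alone (camera adjusted p = 0.105), with the testis-type copies COX4L (-4.89 ± 0.65), CG31644, UQCR-14L and ATPsynCF6L (1 count, against 93.8 CPM in WT) smallest in adjusted p. In the temporal identity list chinmo, Imp, lin-28 and br rose and Syp and Eip93F fell, of 9, and adjusted over the list alone 4 rose and 3 fell (camera adjusted p = 0.472). The RNA-binding protein gene Imp went from 141 to 689 CPM, Syp from 760.5 to 113 CPM and Eip93F had a log2 change of -4.99 ± 0.65 (-5.66 without Upd 1). dsx, the last switch of somatic sex, rose from 46.2 ± 16.9 to 360 ± 62.1 CPM (2.96 ± 0.51, edgeR adjusted p = 0.00012). It was the 1 sex determination gene of 12 that passed, also adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.388 with an estimated correlation). tra, which acts above dsx in females, had a log2 change of 1.82 ± 0.92 (edgeR adjusted p = 0.131).

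The remaining lists were not called in Upd. Of 21 septate junction genes dlg1 and l(2)gl rose and nrv2 (78.2 against 679.5 CPM), cold, Nrx-IV and Lac fell, also adjusted over the list alone (camera adjusted p = 0.866), where l(2)gl and Lac were chosen after their values were seen. Size-factor scaling gave 2 and 5, and upper-quartile scaling 3 and 4. Of 20 matrix and integrin genes LanA (828 against 197 CPM), LanB1, LanB2, mew and BM-40-SPARC rose, also adjusted over the list alone (camera adjusted p = 0.141), the last chosen after its values were seen. Of 14 ecdysone response genes br, ftz-f1 and Eip75B rose and Eip55E and ImpL3 fell, also adjusted over the list alone (camera adjusted p = 0.221), with Eip75B chosen after its values were seen. Of 8 heat shock genes Hsp23 (196 against 2409 CPM) and stv fell, and 1 adjusted over the list alone (camera adjusted p = 0.472). Of 12 muscle markers Strn-Mlck rose and Act87E (5.59, 0.701 and 0.624 CPM in Upd 1, 2 and 3 against 157 CPM), Mlc2 and TpnC73F fell, 1 and 4 adjusted over the list alone (camera adjusted p = 0.668). The hemocyte gene crq fell (1 of 4, camera adjusted p = 0.853), the fat body gene Apoltp rose (1 of 4, 0.472), elav and para rose and nSyb fell among 6 neuron markers (0.488), and br and dec-1 rose and Fas3 fell among 8 follicle cell genes (0.472), each as many adjusted over the list alone. The follicle cell list had a median of -1.16, a mean of 0.39 and an upward camera direction. Without WT 2 its median was 2.70. Only 1 accessory gland marker of 12 and 2 antimicrobial genes of 17 were measured, too few for a list test, and of these PGRP-SA fell. Calls in these lists that 1 library decided had the following edgeR adjusted p. elav, Strn-Mlck and stv ranged from 0.0571 to 0.135 without WT 1, WT 2, WT 3, Upd 1, Upd 2 or Upd 3. LanB1 (without WT 2, WT 3 or Upd 1), LanB2 (WT 2, WT 3, Upd 1 or Upd 3) and mew (WT 1, WT 2 or Upd 1) ranged from 0.0531 to 0.0963. ftz-f1 (WT 1 or WT 3), ImpL3 (WT 1, Upd 1 or Upd 2), Nrx-IV (WT 1 or Upd 2), para (WT 1 or WT 3) and Apoltp (WT 1 or WT 2) ranged from 0.0505 to 0.0954. PGRP-SA (WT 1, WT 2, Upd 2 or Upd 3) ranged from 0.0521 to 0.126 and Fas3 (WT 2 or Upd 2) from 0.0502 to 0.0642.

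Across 10056 tested genes edgeR called 927 higher and 2546 lower in Upd than in WT at an adjusted p of 0.05. The libraries of the 2 groups did not overlap for 67.5% of genes, where chance gives 10%. The widest rises by the fixed rule were wrapper (no count in WT, 54.3, 22.8 and 34.0 CPM in Upd 1, 2 and 3), ovo (7.34 ± 1.23), Her (67.6 CPM, 3 counts over WT), lin-28 (45.9 CPM, 3 counts over WT), bam and E(spl)m3-HLH (5.76 ± 1.44, and 5.17 without WT 2, with its 4 WT counts all in WT 3). The widest falls were ProtA, laf, GluRIIC and Acyp, without a count in Upd, and RacGAP84C and tomboy20, with 1 count each. In WT laf lay at 64.1 ± 18.0 CPM, GluRIIC at 63.2 ± 13.3 CPM, RacGAP84C at 134.5 CPM and tomboy20 at 164 CPM. WT 2 held the highest levels of ProtA (35.4, 178 and 77.4 CPM) and Acyp (32.9, 82.4 and 18.5 CPM in WT 1, 2 and 3). With a germline score in the model 677 were higher and 1251 lower, and E(spl)m3-HLH, lin-28, Nep4, br, CG10176, cold, elav, Fas3, LanB1, Mlc2, PGRP-SA, rpr, Strn-Mlck and TpnC73F lost their calls (edgeR adjusted p from 0.0501 to 0.604). The count of higher genes was 442 without WT 2, 515 without WT 3, 544 without Upd 1, 576 without Upd 2 and 590 without Upd 3, and 2310 with only the 2 groups compared. Fry, which asks whether the genes of a list move one way on balance, passed the 7 lists camera called (adjusted p from 2.4e-05 to 0.0069). It also passed JAK/STAT (0.0379), differentiating cyst cells (0.00071), heat shock (0.0017) and oxidative phosphorylation (0.0010), which camera did not call.

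**Figure D3:**
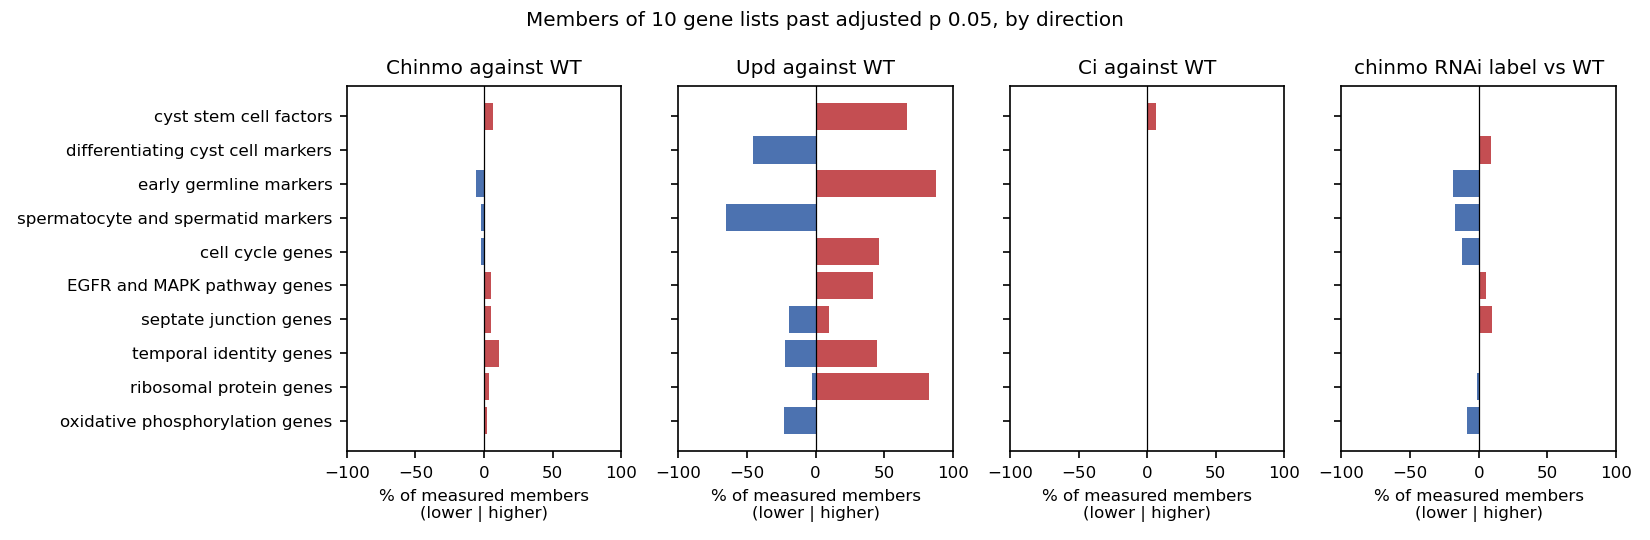
Percent of the measured members of 10 fixed gene lists past an adjusted p of 0.05 in each comparison with WT, higher members to the right in red and lower members to the left in blue. In Upd 14 of 16 early germline markers were higher and 26 of 40 spermatocyte and spermatid markers lower.

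The comparison of Chinmo with WT asked what extra chinmo changes in the cyst lineage. Genes of the male germ line and of mitosis were among those that fell. fzo, a mitofusin gene of spermatids, went from 121 ± 33.7 to 9.19 ± 9.17 CPM (SD, n = 3), a log2 change of -3.63 ± 0.87 (SE, edgeR adjusted p = 0.0365). bora, an activator of Aurora A, and tut, a germline translational repressor, had no count in Chinmo, which allows up to 0.904 CPM from 3 counts over the group, and lay at 36.5 ± 25.6 and 11.1 ± 4.72 CPM in WT. ATPsynC, an ATP synthase subunit, rose from 1136 ± 290 to 2857 ± 685 CPM (1.33 ± 0.32, edgeR adjusted p = 0.0371). The BMP ligand gene dpp lay at 264, 212 and 753 CPM against 85.7 ± 25.6 CPM (2.25 ± 0.60, edgeR adjusted p = 0.0479). Readouts of the other pathways had log2 changes of 0.03 ± 0.81 (zfh1), -0.11 ± 1.02 (tj), -0.41 ± 0.53 (eya), -0.18 ± 0.62 (Socs36E) and -1.15 ± 0.50 (dsx), none past the threshold. Single libraries set these values for zfh1 (-3.15 without Chinmo 1, edgeR adjusted p = 0.0389), tj (2.17 without WT 1 and -2.51 without Chinmo 2) and Socs36E (0.40 without WT 2). For each Chinmo gene given as past the threshold, edgeR adjusted p was 0.0702 to 0.135 without WT 1, 0.165 to 0.210 without WT 2 and 0.127 to 0.183 without WT 3. Without Chinmo 3 it was 0.108 for ATPsynC, 0.149 for dpp and 0.0561 for tut, while fzo (0.0408) and bora (0.0496) passed. The log2 change of dpp was then 1.21 and that of ATPsynC 0.86, and fzo stood at -4.47 without Chinmo 1.

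Of 40 spermatocyte and spermatid markers 1 fell in Chinmo (fzo), and 9 adjusted over the list alone (camera adjusted p = 2.6e-06; adjusted p = 0.699 with an estimated correlation). Of 16 early germline markers 1 fell (tut), and 8 adjusted over the list alone (camera adjusted p = 0.252, and 0.0419 without WT 2). Of 41 cell cycle genes 1 fell, the kinase gene aurA (-4.51 ± 1.21), and 4 adjusted over the list alone (camera adjusted p = 0.061, with 0.00786 without WT 2 and 0.0302 without Chinmo 2). Of 87 ribosomal protein genes RpL31 (1.31 ± 0.36), RpS5a (1.73 ± 0.46) and sta (1.72 ± 0.46) rose, and adjusted over the list alone 16 rose and 1 fell (camera adjusted p = 4.2e-11; adjusted p = 0.699 with an estimated correlation). With size-factor scaling edgeR called none of them, and with upper-quartile scaling 12. Of 83 oxidative phosphorylation genes ATPsynC and COX4 rose, also adjusted over the list alone (camera adjusted p = 0.0035; adjusted p = 0.699 with an estimated correlation). Of 21 septate junction genes Cont rose, also adjusted over the list alone (camera adjusted p = 0.0030; adjusted p = 0.699 with an estimated correlation), though not with size-factor scaling. Without Chinmo 3 the septate (camera adjusted p = 0.0626) and oxidative phosphorylation (0.0998) calls were lost. RpL31, RpS5a, sta, COX4 and Cont then stood at 0.57, 0.44, 0.57, 0.59 and 0.27 on the log2 scale (edgeR adjusted p from 0.226 to 0.632). With a germline score in the model their log2 changes turned negative, at -0.27, -0.79, -0.62, -1.06 and -0.99 in that order (edgeR adjusted p from 0.766 to 0.880). aurA, whose 6 counts in Chinmo were all in Chinmo 2, lost its call without Chinmo 1 (0.0754, with a log2 change of -3.92) or Chinmo 3 (0.0736). edgeR called 0 genes without WT 1, WT 2 or WT 3 (adjusted p from 0.0765 to 0.201 for the genes named here), with 809, 708 and 743 higher and 1686, 977 and 1171 lower at an unadjusted p under 0.05, where DESeq2 called 407 higher and 1210 lower with all libraries.

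The other lists were not called in Chinmo. chinmo was the 1 member past the threshold among 15 JAK/STAT genes (2 adjusted over the list alone, camera adjusted p = 0.286), 15 cyst stem cell factors (1, 0.505) and 9 temporal identity genes (1, 0.635). dpp was the 1 member among 16 Hedgehog genes (1 adjusted over the list alone, camera adjusted p = 0.236), 8 hub markers (2, 0.635) and 12 BMP genes (2 higher and 1 lower, 0.505). sty, a MAPK antagonist, rose among 19 EGFR genes (2 adjusted over the list alone, camera adjusted p = 0.573) and Hsp26 among 8 heat shock genes (2 higher and 1 lower, 0.236). Lists without a member past the threshold over all genes gave, adjusted over the list alone, 1 higher and 1 lower for muscle, 1 higher for hemocytes, 1 lower for the fat body, 1 higher and 2 lower for sex determination, 1 higher for matrix and integrins, 2 higher for ecdysone response and 1 higher for JNK and cell death. Neurons, follicle cells and differentiating cyst cells gave 0, and these 10 lists had camera adjusted p from 0.236 to 0.898. Camera pointed upward against a negative median and mean for the hub, muscle, neuron, follicle cell, matrix, temporal identity and JNK lists. Median and mean differed in sign for the cyst stem cell (-0.11 and 0.16), differentiating cyst cell (0.22 and -0.10), EGFR (0.04 and -0.02) and BMP lists (0.06 and -0.22). These medians changed sign with 1 library left out. They went to 0.15 for cyst stem cells (Chinmo 3) and to -0.76 and -0.28 for differentiating cyst cells (Chinmo 2 and 3). They lay at -0.68 to -0.02 for EGFR (any but WT 3) and -0.27 to -0.11 for BMP (WT 1, WT 3, Chinmo 2 or 3). So did those of the neuron (0.30), follicle cell (1.38) and JNK lists (0.11) without WT 2, and that of the JNK list without Chinmo 3 (0.01). chinmo, dpp, sty and Hsp26 lost their calls without WT 1, WT 2 or WT 3 (edgeR adjusted p from 0.0921 to 0.200). Without Chinmo 3 edgeR adjusted p was 0.0918 for chinmo, 0.149 for dpp, 0.948 for sty and 0.182 for Hsp26, with log2 changes of 1.51, 1.21, -0.06 and 0.74. In the model with a germline score sty stood at -1.70 (edgeR adjusted p = 0.766).

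edgeR called 176 genes higher and 106 lower in Chinmo than in WT, and 28.6% of genes had groups that did not overlap, where chance gives 10%. The widest rises had their highest level in Chinmo 3. HGTX, a homeobox gene, lay at 11.7, 2.63 and 701 CPM in Chinmo 1, 2 and 3, HIP at 23.4, 15.8 and 706 CPM, GstE9 at 118, 43.5 and 359 CPM and IM2, an immune peptide, at 26.7, 12.5 and 276 CPM. ItgaPS4 lay at 8.34, 6.59 and 213 CPM and PPO1, a prophenoloxidase, at 163 CPM in Chinmo 3 with 3 counts over WT. Without Chinmo 3 the first 5 had log2 changes of 3.11, 0.99, 3.40, 3.48 and 2.11, and none of the 6 passed (edgeR adjusted p from 0.088 to 0.498). The widest falls were bora, Dop2R (25.3 ± 4.01 CPM in WT), Cpr66Cb and mtg, without a count in Chinmo, with sti (1 count, 21.0 CPM in WT) and BigH1 (3 counts, 34.4 CPM in WT). WT 2 held the highest levels of Cpr66Cb (1.54, 66.05 and 7.60 CPM in WT 1, 2 and 3) and mtg (8.21, 43.0 and 13.3 CPM). Cpr66Cb and mtg lost their calls without Chinmo 3 (0.0762 and 0.0531) and Cpr66Cb without Chinmo 1 (0.0509). Counts of higher and lower genes were 27 and 53 without Chinmo 3, 421 and 131 without Chinmo 1, and 484 and 403 without Chinmo 2. With only these 2 groups in the model edgeR called 1 and 0 (644 and 553 at an unadjusted p under 0.05), and with a replicate block 11 and 0 (817 and 1276), where DESeq2 called 407 and 1210 and limma-voom 197 and 645 with all libraries. No call named here held without WT 1, WT 2 or WT 3 (edgeR adjusted p from 0.0702 to 0.210). With a germline score edgeR called 0 higher and 0 lower, with 434 and 178 at an unadjusted p under 0.05. HGTX and HIP then stood at -0.65 and -0.94. The share of calls that were higher was 62.4% with TMM scaling, 38.9% with size factors and 72.5% with the upper quartile, which moved the median of all genes by -0.29 and 0.12 on the log2 scale. Of the 4 lists camera called, fry passed the spermatocyte and spermatid list (adjusted p = 0.0413). Its adjusted p was 0.316 for ribosomal proteins, 0.4335 for septate junctions and 0.770 for oxidative phosphorylation.

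The comparison of Ci with WT asked what activated Hedgehog signalling changes in these cells. CySC genes stood higher as a list, with ptc at 43.7 ± 3.22 against 7.55 ± 2.93 CPM (SD, n = 3, log2 change 2.52 ± 0.92, SE), tj at 46.9 ± 13.7 against 6.34 ± 9.20 CPM and zfh1 at 77.5 ± 41.4 against 15.9 ± 6.78 CPM (2.29 ± 0.81). Each of these 3 had an edgeR adjusted p of 1 over all genes. Of 15 cyst stem cell factors 1, the transgene ci, passed over all genes and 6 adjusted over the list alone. Camera's adjusted p was 6.9e-13, and 0.042 with an estimated correlation. Of the fixed lists this was the 1 call against WT that held with an estimated correlation, and fry did not pass it (adjusted p = 0.0554). Of 16 Hedgehog genes ci passed, also adjusted over the list alone (camera adjusted p = 0.0095; adjusted p = 0.315 with an estimated correlation), and the call was lost once members held by other lists were left out (0.618). chinmo stood at 155.5 ± 50.8 CPM (1.11 ± 0.51), dsx at 116.5 ± 53.7 CPM (1.34 ± 0.49), Socs36E at 0.71 ± 0.61 and eya at -0.41 ± 0.53 on the log2 scale. Like the ci call, the Hedgehog call was lost without WT 2 (camera adjusted p = 0.105), WT 3 (0.0536) or Ci 1 (0.233). Without Ci 1 the list's log2 median went from 0.27 to -0.06.

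Ribosomal protein genes stood lower in Ci as a list, with a median log2 change of -0.45 over 87 genes (camera adjusted p = 2.9e-13; adjusted p = 0.434 with an estimated correlation). Without Ci 1 that median was -0.73. Also lower as lists were 83 oxidative phosphorylation genes (camera adjusted p = 0.015, and 0.642 with an estimated correlation). So were 21 septate junction genes (0.040 and 0.664). Higher as lists were 16 early germline markers (camera adjusted p = 0.0047; adjusted p = 0.315 with an estimated correlation) and 19 EGFR and MAPK genes (camera adjusted p = 0.012; adjusted p = 0.388 with an estimated correlation). The same held for 9 temporal identity genes (camera adjusted p = 0.016; adjusted p = 0.178 with an estimated correlation) and 41 cell cycle genes (camera adjusted p = 0.019; adjusted p = 0.664 with an estimated correlation). In these 7 lists edgeR called 0 members, also adjusted over the list alone. Left-out libraries ended the calls for septate junctions (WT 1, 0.410, and Ci 2, 0.949, where the median went from -0.16 to 0.09), early germline (WT 2, 0.105, and Ci 2, 0.217), cell cycle (WT 2, 0.244, and Ci 2, 0.265), EGFR (WT 3, 0.0734, and Ci 1, 0.346), temporal identity (WT 2, 0.160, and Ci 1, 0.0518) and oxidative phosphorylation (Ci 2, 0.148). Without members held by other lists the septate junction (0.0763) and temporal identity (0.414) calls ended. Fry passed neither these lists nor the Hedgehog list (adjusted p = 0.0554 for temporal identity and 0.407 to 0.7435 for the others). The other 15 lists tested were not called, with the fat body called without Ci 1 (0.00723). Over all genes edgeR called 1 higher, ci, and 0 lower. At an unadjusted p under 0.05 it gave 128 and 125 (502.8 by chance), and 373 and 245 with Chinmo 3 left out of the fit. Few calls thus do not show few changes. DESeq2 called 1 and 0, limma-voom 3 and 0, and 18 and 20 with quality weights. The edgeR count was 0 without WT 1, WT 2, WT 3 or Ci 1, with 183, 123, 151 and 123 higher and 121, 92, 116 and 203 lower at an unadjusted p under 0.05. Median, mean and camera direction did not share 1 sign for the spermatocyte and spermatid, muscle, follicle cell and JNK lists. Their medians of -0.01, -0.08, -0.05 and 0.03 changed sign with 1 library left out, to between -0.12 and 0.63. The libraries were WT 2 or Ci 1 for the first, WT 2 or Ci 3 for muscle and follicle cells, and WT 1, WT 3, Ci 2 or Ci 3 for JNK.

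The libraries labelled chinmo RNAi were compared with WT to ask what loss of chinmo changes, with the limit that chinmo was not measured as lower in them. Of 40 spermatocyte and spermatid markers 7 fell and 33 did not pass (camera adjusted p = 3.9e-08; adjusted p = 0.256 with an estimated correlation). Mst77F went from 919 ± 280 to 230 ± 38.3 CPM (SD, n = 3), lower in all 3 libraries (edgeR adjusted p = 0.0084), and bol, a regulator of meiotic entry, from 615 to 95.7 CPM (log2 change -2.68 ± 0.72, SE). shg, the E-cadherin gene, rose from 193 ± 38.1 to 532 ± 255 CPM (1.46 ± 0.41), and the septate junction genes Lac from 194 to 721 CPM (1.89 ± 0.50) and scrib from 322 to 794 CPM (1.30 ± 0.36). dsx stood at 82.1 ± 18.6 CPM (0.83 ± 0.48, edgeR adjusted p = 0.315), tra at 0.83 ± 0.91, eya at -0.26 ± 0.53, zfh1 at 0.89 ± 0.79 and ptc at 1.69 ± 0.90 on the log2 scale, and Yp1, a yolk protein gene, was below the count filter. With 1 library left out, calls were lost for Mst77F without chinmo RNAi 1 or 2 (edgeR adjusted p = 0.0516 and 0.062) and for bol without WT 2, WT 3, chinmo RNAi 1 or 2 (0.0814 to 0.129), which stood at -3.75 without chinmo RNAi 3. bol, a member of the germline score, stood at 0.75 with that score in the model (edgeR adjusted p = 0.666). They were lost for shg and Lac without any of WT 1, WT 2, WT 3, chinmo RNAi 1 or 2 (0.0523 to 0.205) and for scrib without any of the 6 (0.0606 to 0.136).

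Of 40 spermatocyte and spermatid markers 7 fell in this label, and 17 adjusted over the list alone, with Mst84Dc at 463 against 586.5 CPM (edgeR adjusted p = 0.657) among those that did not pass. Of 41 cell cycle genes CycB3, aurA, pim, polo (-2.64 ± 0.75) and fzy fell, the last chosen after its values were seen, and 8 adjusted over the list alone (camera adjusted p = 0.0053; adjusted p = 0.295 with an estimated correlation). Of 83 oxidative phosphorylation genes 7 fell, and 8 adjusted over the list alone (camera adjusted p = 0.010; adjusted p = 0.295 with an estimated correlation), led by testis-type copies such as ATPsynCF6L (-6.12 ± 1.11, its 7 counts all in chinmo RNAi 3) and COX4L (-2.73 ± 0.59). That list was not called without chinmo RNAi 1 (camera adjusted p = 0.105). Of 16 early germline markers tut (no count, which allows up to 0.594 CPM from 3 counts over the group, and 11.1 ± 4.72 CPM in WT), bgcn and AGO3 fell, and 6 adjusted over the list alone (camera adjusted p = 0.063, and 0.00819 without WT 2). Of 21 septate junction genes Lac and scrib rose, also adjusted over the list alone (camera adjusted p = 4.9e-05; adjusted p = 0.256 with an estimated correlation). shg rose among 8 hub markers, 3 adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.256 with an estimated correlation), and among 11 differentiating cyst cell markers (1, camera adjusted p = 0.429), while size-factor scaling gave no call among the hub markers and 1 lower gene in the other list. aos, an EGFR antagonist, rose among 19 EGFR genes (3.96 ± 1.16, also adjusted over the list alone, camera adjusted p = 0.010; adjusted p = 0.256 with an estimated correlation). Left-out libraries ended calls for CycB3, aurA and AGO3 (WT 2, WT 3, chinmo RNAi 1 or 2, edgeR adjusted p from 0.0564 to 0.152), pim and tut (chinmo RNAi 1 or 2, 0.0595 to 0.0698) and COX4L (WT 2, chinmo RNAi 1 or 2, 0.0579 to 0.0676). The log2 change of aos was 4.72 without WT 2 and that of polo -3.30 without chinmo RNAi 2. Left-out libraries also ended calls for polo and bgcn (WT 2, WT 3, chinmo RNAi 1, 2 or 3, 0.0628 to 0.137), for aos, shg and Lac (any but chinmo RNAi 3, 0.0523 to 0.205) and for scrib (any, 0.0606 to 0.136).

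Further lists stood higher in this label with 0 members past edgeR's threshold, over all genes or adjusted over the list alone. They were the cyst stem cell factors and the JNK and cell death genes (both camera adjusted p = 0.0053; adjusted p = 0.256 with an estimated correlation) and the BMP genes (camera adjusted p = 0.0080; adjusted p = 0.256 with an estimated correlation). Sex determination genes (camera adjusted p = 0.024; adjusted p = 0.295 with an estimated correlation), JAK/STAT genes (0.040; adjusted p = 0.295 with an estimated correlation), Hedgehog genes (0.040; adjusted p = 0.289 with an estimated correlation) and matrix and integrin genes (0.048; adjusted p = 0.339 with an estimated correlation) followed. These last 4 calls were lost without WT 3 (camera adjusted p = 0.0641, 0.0808, 0.0641 and 0.0641). JAK/STAT was also lost without WT 1, chinmo RNAi 1 or 3 (0.0874, 0.140 and 0.0651), Hedgehog without WT 2 or chinmo RNAi 3 (0.0733 and 0.0642) and the matrix list without WT 2 or chinmo RNAi 1 (0.0765 and 0.107). Once members held by other lists were left out, the calls of cyst stem cell factors (camera adjusted p = 0.176), JAK/STAT (0.320), Hedgehog (0.331) and matrix genes (0.107) ended. The last also ended with a replicate block (0.0565). Not called were follicle cells (0 of 8, camera adjusted p = 0.063), hemocytes (0 of 4, 2 adjusted over the list alone, 0.083), ecdysone response (0 of 14, 0.083), neurons (0 of 6, 1 adjusted over the list alone, 0.174), temporal identity (0 of 9, 1 adjusted over the list alone, 0.174), heat shock (0 of 8, 0.306) and fat body (0 of 4, 0.717). Calls appeared for follicle cells without WT 1, WT 2 or chinmo RNAi 2 (0.00634 to 0.0477), hemocytes without WT 1 or chinmo RNAi 2 (0.0466 and 0.0292), neurons without WT 2 (0.0374) and ecdysone response without WT 1 (0.0477). Tm1 rose among 12 muscle markers (1.49 ± 0.38, also adjusted over the list alone, camera adjusted p = 0.595), a list with a median of -0.29, a mean of -0.39 and an upward camera direction. Without WT 3 its median was 0.14. Of 87 ribosomal protein genes RpS19b fell (-3.69 ± 1.09, its 12 counts all in chinmo RNAi 3) and 0 adjusted over the list alone, with a median of 0.13, a mean of -0.05 and, with size-factor scaling, a median of -0.15, and with -0.01 and -0.03 without WT 2 and chinmo RNAi 2 (camera adjusted p = 0.162, with 0.0477 without WT 1 and 0.0103 without chinmo RNAi 1). Tm1 and RpS19b lost their calls without WT 1, WT 2, WT 3, chinmo RNAi 1 or 2 (edgeR adjusted p from 0.0507 to 0.143). RpS19b stood at 0.17 with a germline score (edgeR adjusted p = 0.962).

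edgeR called 139 genes higher and 541 lower in the libraries labelled chinmo RNAi than in WT, and groups did not overlap for 36.1% of genes, where chance gives 10%. spz5, a neurotrophin-like ligand, rose from 15.9 ± 8.29 to 252 ± 58.8 CPM (3.98 ± 0.98), nord by 5.07 ± 1.38, Ance-2 by 4.75 ± 1.38 and boss by 4.31 ± 1.25 on the log2 scale. spz5 stood at -0.29 with a germline score (edgeR adjusted p = 0.913). The 4 WT counts of nord were all in WT 1, and it stood at 4.47 without WT 2. The 14 WT counts of Ance-2 were all in WT 2, and it stood at 4.05 without WT 1. Without chinmo RNAi 2 boss stood at 3.42. Gfat1 lay at 27.6, 91.2 and 35.6 CPM in the 3 libraries with 1 count over WT, and Cpr62Bc at 96.2, 21.8 and 15.5 CPM with 3. The widest falls had no count in this label. They were Prosbeta5R2 and Prosbeta4R1, proteasome subunits of the testis (62.9 ± 20.5 and 36.9 ± 12.6 CPM in WT), Tsp33B (50.05 ± 28.3 CPM), Ssl (42.35 ± 13.4 CPM), PPYR1 (34.9 ± 17.0 CPM) and ZnT35C (10.8, 29.0 and 63.2 CPM in WT 1, 2 and 3). Calls ended for boss without any 1 of the 6 libraries (edgeR adjusted p from 0.0509 to 0.157), for spz5 and Cpr62Bc without WT 1, WT 2, WT 3, chinmo RNAi 1 or 2 (0.0595 to 0.126) and for nord without WT 2, WT 3, chinmo RNAi 1 or 2 (0.0734 to 0.132). The same held for Ance-2 without WT 1, WT 3, chinmo RNAi 1 or 2 (0.0949 to 0.149), Gfat1 without WT 2 or chinmo RNAi 2 (0.052 and 0.0606), Ssl and ZnT35C without chinmo RNAi 1 or 2 (0.0544 to 0.0634) and Prosbeta5R2 without chinmo RNAi 2 (0.0501). Higher and lower counts were 34 and 450 without WT 1, 21 and 93 without WT 2, 18 and 149 without WT 3, 26 and 47 without chinmo RNAi 1, 6 and 29 without chinmo RNAi 2, and 99 and 493 without chinmo RNAi 3. They were 73 and 285 with a replicate block, 469 and 919 with only the 2 groups compared and 1 and 2 with a germline score, and the share of calls that were higher was 20.4% with TMM scaling and 10.0% with size factors, which moved the median of all genes by -0.29. Of the 13 lists camera called, fry passed 7 (septate junctions, hub, spermatocyte and spermatid, cell cycle, BMP, JNK and cell death, and oxidative phosphorylation, adjusted p from 0.0235 to 0.0372). It did not pass cyst stem cell factors and EGFR (both 0.0630), Hedgehog (0.0801), sex determination (0.0896), JAK/STAT (0.159) and matrix genes (0.234). It passed early germline (0.0285) and follicle cell genes (0.0418), which camera did not call.

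Direct tests compared the manipulated groups with each other. dsx was lower in Chinmo than in each of the other 3, with log2 differences of -4.12 ± 0.55 against Upd (SE, edgeR adjusted p = 5.1e-06), -2.49 ± 0.52 against Ci (0.0085) and -1.99 ± 0.51 against the libraries labelled chinmo RNAi (0.0366). zfh1 was higher in Upd than in Ci (2.55 ± 0.80, edgeR adjusted p = 0.0175) and eya lower (-2.48 ± 0.56, 0.0015), while the differences in ptc (-0.16 ± 0.85, 0.91) and ci (-0.60 ± 0.48, 0.386) did not pass. vas was higher in Upd than in Ci (4.08 ± 0.85) and lower in Chinmo than in Upd (-8.34 ± 1.13), and Mst77F ran the other way (-5.93 ± 0.47 and 5.64 ± 0.46). chinmo stood 1.83 ± 0.52 higher in Chinmo than in the libraries labelled chinmo RNAi (edgeR adjusted p = 0.0499) and at -0.54 ± 0.51 relative to Upd (0.41). Single-gene values of these direct tests were not rerun without single libraries.

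In Upd relative to Ci 13 of 16 early germline markers were higher, also adjusted over the list alone (camera adjusted p = 1.5e-07; adjusted p = 0.0646 with an estimated correlation), and 26 of 40 spermatocyte and spermatid markers lower, 27 adjusted over the list alone (1.3e-13; adjusted p = 0.191 with an estimated correlation). There 81 of 87 ribosomal protein genes were higher and 1 lower, 82 and 1 adjusted over the list alone (camera adjusted p = 1.2e-28; adjusted p = 0.191 with an estimated correlation). In Chinmo relative to Upd 32 of 41 cell cycle genes were lower, 33 adjusted over the list alone (camera adjusted p = 6.4e-11; adjusted p = 0.141 with an estimated correlation). Of 15 cyst stem cell factors 10 were lower there and 1 higher, 11 and 1 adjusted over the list alone (camera adjusted p = 8.5e-05; adjusted p = 0.191 with an estimated correlation). Oxidative phosphorylation genes were higher in Chinmo than in Upd (34 of 83, 36 adjusted over the list alone, camera adjusted p = 0.00027; adjusted p = 0.312 with an estimated correlation) and than in the libraries labelled chinmo RNAi (9 of 83, 21 adjusted over the list alone, 2.9e-10; adjusted p = 0.128 with an estimated correlation). Sex determination genes were lower in Chinmo than in Upd (5 of 12, 6 adjusted over the list alone, camera adjusted p = 0.0071; adjusted p = 0.312 with an estimated correlation) and than in the libraries labelled chinmo RNAi (3 of 12, 5 adjusted over the list alone, 0.0076; adjusted p = 0.345 with an estimated correlation). The last call was lost without Chinmo 2 (camera adjusted p = 0.0857). Fry passed each list given here (adjusted p from 3.7e-05 to 0.0101).

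Higher and lower genes numbered 2435 and 1450 for Chinmo relative to Upd, with 948 lower without Upd 1. For Chinmo relative to Ci they were 499 and 313, moving to 234 and 480 without Chinmo 3, 712 and 657 without Chinmo 2, 26 and 15 without Ci 2, and 90 and 43 without Ci 3. The share higher there was 61.5% with TMM scaling and 36.7% with size factors. Upd relative to Ci gave 581 and 2368, with 304, 326 and 320 higher without Upd 1, 2 and 3 and 348, 341 and 226 without Ci 1, 2 and 3. Chinmo relative to the libraries labelled chinmo RNAi gave 224 and 156, moving to 367 and 164 without Chinmo 1, 433 and 282 without Chinmo 2, 4 and 11 without chinmo RNAi 1, 21 and 75 without chinmo RNAi 2, and 85 and 85 without chinmo RNAi 3.

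Overlaps asked whether the manipulations moved the same genes. Chinmo and the libraries labelled chinmo RNAi, a gain and a labelled loss of chinmo, shared 14 higher genes (2.43 expected for independent lists) and 46 lower ones (5.70 expected), aurA, fzo and tut among the latter. These 60 became 0 without WT 1, WT 2 or WT 3, where Chinmo had no calls, 150 without Chinmo 2, and 16, 14 and 38 without chinmo RNAi 1, 2 and 3. With a germline score they were 0. edgeR called 0 genes in opposite directions (3 without Chinmo 1 and 1 without Chinmo 2), where independent lists give 9.47 and 1.47. DESeq2 gave 9, limma-voom 1 and quality weights 5. At an unadjusted p under 0.05, 32 were opposite and 903 alike, where 40 simulations of unchanged groups gave at most 3 and 245. Chinmo and that label had 2416 and 2320 such genes (502.8 by chance), so these simulations set no scale. Upd shared 406 lower and 19 higher genes with that label (137 and 12.8 expected). Opposite were 62 lower in Upd and 8 higher (35.2 and 49.9 expected). With Chinmo it shared 56 lower and 19 higher genes (26.8 and 16.2 expected). Opposite were 38 lower in Upd and 10 higher (44.6 and 9.77 expected). With 1 gene called in Ci, the edgeR calls cannot show whether Chinmo, Upd and Ci moved the same genes. They had 0 in common, also with DESeq2 and limma-voom (1 and 3 calls in Ci), and 4 with quality weights (38). At an unadjusted p under 0.05 they had 25, chinmo and ci among them, where the simulations gave a mean of 32.4 and a highest of 51. Chinmo, Upd and Ci had 2416, 4380 and 253 genes at that p (502.8 by chance), so the simulations set no scale here either. The covariance of log2 changes across genes, which are not independent replicates, was 1.74 for Chinmo and the libraries labelled chinmo RNAi (0.474 simulated), 2.71 for Upd and that label (0.467), 1.41 for Chinmo and Upd (0.465), 0.899 for Upd and Ci (0.469), 0.266 for Chinmo and Ci (0.470) and 0.350 for Ci and that label (0.469). In the same order Pearson's r was 0.444 (0.450 simulated), 0.430 (0.4945), 0.236 (0.459), 0.321 (0.512), 0.1525 (0.460) and 0.190 (0.493). All pairs share the 3 WT libraries. Covariances of 0.266 and 0.350 lay below the simulated ones, so these do not isolate what sharing adds.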

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

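The tests of swapped labels, of the share of cyst stem cell RNA and of a lower share of cyst cell RNA were chosen after the results they measure had been seen, and the other tests in this part before.

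Reads that fell in no annotated gene were looked at because they lie outside the comparisons. Their share was 15.78% in Upd (15.1% to 17.0% over 3 libraries) and 10.2% in WT (9.55% to 10.8%), with 11.2% in Ci, 11.9% in chinmo RNAi and 9.71% in Chinmo.

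The 6 libraries of a comparison split in 10 ways, too few for a share under 0.05. As 9 ways mix both groups, chance was not measured. The real split called 282 genes in Chinmo, 3473 in Upd, 1 in Ci and 680 in chinmo RNAi against WT. The highest other split called 0 in each. For the direct comparisons the real and highest other counts were 3885 and 552 (Chinmo to Upd), 812 and 0 (Chinmo to Ci), 2949 and 0 (Upd to Ci) and 380 and 220 (Chinmo to chinmo RNAi). Camera called 4 lists in Chinmo (highest other split 4, as many in 3 of 10), 7 in Upd (11, in 8 of 10), 9 in Ci (10, in 3 of 10) and 13 in chinmo RNAi (6, in 1 of 10).

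The library Chinmo 3 had a count for 4983 genes. The other 14 libraries, thinned to its total in 20 draws each, had 7863 genes or more, and thinned to its total without ribosomal RNA genes 7747 or more against 4972, so neither its lower total nor ribosomal RNA accounts for the whole gap. Few RNA molecules entering the library may explain it. Of 73 genes of the mitochondrial ribosome, which most cells express, 53.4% had no count there and 1.37% to 22.3% in the thinned others. Chinmo RNAi 2 and 1 (22.3% and 8.97%) and Chinmo 1 (7.67%) leave this undecided. A real loss of transcripts in these cells was not tested.

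chinmo was not lower in the libraries labelled chinmo RNAi. Swapped labels with WT would leave Dcr-2, whose transgene that genotype carries, without a rise, and its log2 change of 0.71 had a 95% interval of -0.14 to 1.55, which keeps this open. A larger share of cyst stem cell RNA could hide a fall, but chinmo stood -0.20 from the median of the other cyst stem cell factors (0.90), with an interval of -1.20 to 0.80 that does not decide it. Reads from the hairpin counted as chinmo were not tested and stay open, as do the younger age of these flies and a reduction of the protein alone.

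In Upd 14 of 16 early germline markers rose and 26 of 40 spermatocyte and spermatid markers fell. A lower share of cyst cell RNA alone would raise both, unlike the log2 medians of 4.54 and -4.60. Less RNA of late germ cells in the sorted fraction is consistent with a second late list that shares no gene with the first (median -5.83, 12 of 13 fell), where Mst77F and Mst84Db still stood at 919 and 1394 CPM in WT although the sort for somatic GFP should remove germ cells. RNA of early germ cells was tested with a second early list (median 1.67, 5 of 11 rose and 1 fell), which does not decide it, while vas and aub stood at 383 and 268 CPM in Upd. A germ line change with Upd, alone or with a lower cyst cell share, stays open as untested.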

How the results depend on the processing

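Of the alternatives given here, the authors' size factors, quality weights, the fit without Chinmo 3 and the removal of ribosomal RNA genes were chosen after seeing the data. For named genes 2876 alternative values kept their sign and side of the threshold, 479 kept their sign and lost the threshold, 13 passed it only in the alternative, 46 that passed in neither changed sign and 14 that passed in only 1 of the pair reversed. For medians of gene lists 1842 kept both, 102 kept their sign and lost camera's call, 23 gained one, 135 called in neither changed sign and 2 lost the call and changed sign. The last were the Hedgehog list in Ci without Ci 1 (0.27, then -0.06) and the septate list in Ci without Ci 2 (-0.16, then 0.09). With the germline score chinmo stood at -0.27 in chinmo RNAi. Of the counts of genes in the 8 comparisons 165 stayed within 1.5 times the reported count and 139 did not. No value could be had in Chinmo from DESeq2 for HGTX, HIP, ItgaPS4 and sty, which have no adjusted p there, from the fit of 2 groups for Cpr66Cb, HGTX, tj, tra and upd1 (nor for PGRP-SA in Upd and aos in chinmo RNAi), and for hub markers once members of other lists were left out. The stricter filter and the removal of ribosomal RNA genes moved none of them by more. The self-test sets the limit of depth and spread, since it recovered no 2-fold change. Except for scaling, which shifts every log2 change of a library alike, and for settings with fewer libraries or genes, the cause was not tested.

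Counts that moved by more than 1.5 times are given as higher and lower together, relative to WT unless a second group is named. Size-factor scaling (RLE) and the authors' size factors both gave 79 and 124 (Chinmo), 88 and 790 (chinmo RNAi) and 402 and 693 (Chinmo to Ci). They moved the median of all genes by -0.29 on the log2 scale in Chinmo and by -0.29 in chinmo RNAi. Upper-quartile scaling, which moved that median by 0.12 in Chinmo and 0.23 in Upd, gave 480 and 182 (Chinmo), 808 and 387 (Chinmo to Ci) and 376 and 173 (Chinmo to chinmo RNAi). Without the low-count filter there were 422 and 392 (Chinmo), 1 and 1 (Ci), 209 and 853 (chinmo RNAi), 625 and 575 (Chinmo to Ci) and 485 and 282 (Chinmo to chinmo RNAi). DESeq2 called 407 and 1210 (Chinmo), 1585 and 2774 (Upd), 259 and 1419 (chinmo RNAi), 2409 and 2405 (Chinmo to Upd), 643 and 1761 (Chinmo to Ci), 1046 and 2664 (Upd to Ci) and 622 and 598 (Chinmo to chinmo RNAi), and limma-voom 197 and 645 (Chinmo), 1654 and 2691 (Upd), 3 and 0 (Ci), 399 and 1187 (chinmo RNAi), 2054 and 2326 (Chinmo to Upd), 581 and 1331 (Chinmo to Ci), 1319 and 2564 (Upd to Ci) and 117 and 260 (Chinmo to chinmo RNAi). Quality weights gave 2947 and 3528 (Upd), 18 and 20 (Ci), 849 and 1315 (chinmo RNAi), 770 and 724 (Chinmo to Ci), 2901 and 3423 (Upd to Ci) and 67 and 95 (Chinmo to chinmo RNAi).

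The fit without Chinmo 3 gave 27 and 53 (Chinmo), 1532 and 3123 (Upd), 520 and 1443 (chinmo RNAi), 234 and 480 (Chinmo to Ci) and 980 and 3085 (Upd to Ci). Of the 80 genes it called in Chinmo 57 were among the 282 reported. With only the 2 groups compared in the model there were 1 and 0 (Chinmo), 2310 and 3040 (Upd), 3 and 0 (Ci), 469 and 919 (chinmo RNAi), 977 and 830 (Chinmo to Upd), 3 and 0 (Chinmo to Ci), 1790 and 3002 (Upd to Ci) and 1 and 3 (Chinmo to chinmo RNAi). The germline score as a covariate gave 0 and 0 (Chinmo), 677 and 1251 (Upd), 1 and 2 (chinmo RNAi), 0 and 0 (Chinmo to Ci), 342 and 1038 (Upd to Ci) and 204 and 266 (Chinmo to chinmo RNAi). With it the edgeR unadjusted p was under 0.05 for 434 higher and 178 lower genes in Chinmo, and 199 of the 282 reported kept their sign. For the other pairs with a 0 these unadjusted counts were 560 and 243 (germline score, Chinmo to Ci), 817 and 1276 (block, Chinmo), 644 and 553 (2 groups, Chinmo), 270 and 259 (2 groups, Ci) and 760 and 714 (2 groups, Chinmo to Ci). In Upd 1496 of 3473 reported genes were called with it and 3397 kept their sign. The score is built from genes that differ between the groups, so it takes up part of the group difference by construction. With the replicate number as a block (replicate block) there were 11 and 0 (Chinmo), 73 and 285 (chinmo RNAi), 274 and 126 (Chinmo to Ci) and 39 and 50 (Chinmo to chinmo RNAi). Same-number libraries of Chinmo and WT correlated at -0.0574 to 0.0466 and those of Ci and WT at -0.0199 to 0.295, so the numbers do not pair the libraries.

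When libraries were left out 1 at a time, the counts relative to WT ran over 0 to 484 higher and 0 to 403 lower in Chinmo, 442 to 672 higher and 2001 to 2424 lower in Upd, 0 to 1 higher and 0 to 0 lower in Ci and 6 to 99 higher and 29 to 493 lower in chinmo RNAi. Chinmo relative to Upd gave 1751 to 2652 higher and 948 to 1591 lower, Chinmo to Ci 26 to 712 higher and 15 to 657 lower, Upd to Ci 226 to 348 higher and 1865 to 2214 lower and Chinmo to chinmo RNAi 4 to 433 higher and 11 to 282 lower. The count of genes shared by Chinmo, Upd and Ci was 4 with quality weights (38 calls in Ci) and 0 elsewhere, where Ci had 0 to 3 calls, so that 0 says nothing about stability. The count of opposite genes in Chinmo and chinmo RNAi ran from 0 to 3 with 1 library left out, where Chinmo had no calls without WT 1, WT 2 or WT 3. It was 1 with size factors (RLE or the authors'), 8 without the low-count filter, 9 with DESeq2, 1 with limma-voom and 5 with quality weights.

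Reversed values were those of zfh1 in Chinmo without Chinmo 1 (-3.15, where leaving out single libraries gave up to 0.56) and of sty in Chinmo without Chinmo 3 (-0.0648 in both fits, where leaving out single libraries gave up to 3.35). With the germline score the log2 changes in Chinmo were -0.65 (HGTX), -0.94 (HIP), -0.99 (Cont), -1.06 (COX4), -0.27 (RpL31), -0.79 (RpS5a), -0.62 (sta) and -1.70 (sty), and in chinmo RNAi -0.29 (spz5), 0.75 (bol) and 0.17 (RpS19b). Follicle cell genes were called with size factors in chinmo RNAi (camera adjusted p = 0.0483), and JAK/STAT genes in Upd with the replicate block (0.0481).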

Other observations

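The 17 gene groups in this part were chosen after the data were seen, and so was their camera test with each library left out in turn. For the comparisons with WT those that camera called are given, with members past the edgeR threshold, the number adjusted over the list alone in brackets and camera's adjusted p. In Upd the sperm leucyl aminopeptidases, abundant proteins of mature sperm, fell in 7 of 7 [7] genes with a median of -6.12 (camera adjusted p = 3.2e-09; adjusted p = 0.022 with an estimated correlation), and 6 of 6 [6] measured odorant binding protein genes fell (camera adjusted p = 7.3e-05; adjusted p = 0.202 with an estimated correlation). Glutathione S-transferases fell in 13 of 28 [14] (camera adjusted p = 9.5e-05; adjusted p = 0.314 with an estimated correlation) and vacuolar ATPase genes in 14 of 27 [16] (camera adjusted p = 0.0013; adjusted p = 0.314 with an estimated correlation). Of genes on chromosome 4, 20 rose and 6 fell of 75 [20 and 6] (camera adjusted p = 3.4e-05; adjusted p = 0.290 with an estimated correlation). Mitochondrial ribosome genes stood higher with 1 of 70 [0] past the threshold (camera adjusted p = 0.0013; adjusted p = 0.348 with an estimated correlation). Fry passed these 6 groups (adjusted p from 1.4e-06 to 0.0307), and camera's calls held with any 1 library left out. Odorant binding proteins past the threshold were 4, 4 and 3 without Upd 1, 2 and 3, and genes of chromosome 4 that rose were 11, 11, 7 and 12 without WT 2, WT 3, Upd 1 and Upd 3. Those that fell were 3, 2 and 2 without WT 3, Upd 2 and Upd 3. Camera called none of the other 11 groups in Upd (adjusted p from 0.0515 to 0.906), of which fry passed 8. Of these, chromosome Y was called without Upd 2 or Upd 3 (camera adjusted p = 0.0327 and 0.0493).

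In Chinmo, actin and Arp2/3 complex genes rose in 3 of 12 [7] (camera adjusted p = 2.8e-06; adjusted p = 0.044 with an estimated correlation) and proteasome genes in 2 of 31 [6] (camera adjusted p = 0.0017; adjusted p = 0.044 with an estimated correlation). Glutathione S-transferases rose in 2 of 28 [6] (camera adjusted p = 4.2e-05; adjusted p = 0.198 with an estimated correlation) and glycolysis genes in 1 of 12 [2] (camera adjusted p = 0.0018; adjusted p = 0.198 with an estimated correlation). Axonemal dyneins stood lower with 0 members past the threshold of 9 [4] (camera adjusted p = 0.0017; adjusted p = 0.198 with an estimated correlation). Fry did not pass the transferase and glycolysis groups (each adjusted p = 0.105). Chinmo 3 had 4983 genes detected and 32.3% ribosomal RNA, and without it edgeR calls in Chinmo went from 282 to 80. Without it the proteasome lost its group call (median 0.13 from 0.43, camera adjusted p = 0.198), and actin and Arp2/3 genes (2.4e-06), transferases (6.7e-07), glycolysis (0.0034) and axonemal dyneins (0.0049) kept theirs. The members that rose lost edgeR's threshold without Chinmo 3, WT 1, WT 2 or WT 3. Camera's calls did not hold with 1 library left out for the chaperonin (0 of 8 [2], 0.017, then 0.0752 without Chinmo 2), chromosome Y (0 of 13 [2], 0.0035, then 0.110 without Chinmo 1) and sperm leucyl aminopeptidases (0 of 7 [4], 0.044, then 0.164, 0.0912 and 0.170 without WT 2, Chinmo 1 and Chinmo 2). In the libraries labelled chinmo RNAi 5 of 13 [10] genes of the mitochondrial genome fell (camera adjusted p = 0.00095; adjusted p = 0.448 with an estimated correlation). Genes on chromosome Y fell in 2 of 13 [6] there (camera adjusted p = 6.7e-05; adjusted p = 0.189 with an estimated correlation). Sperm leucyl aminopeptidases fell in 2 of 7 [5] (camera adjusted p = 0.0016; adjusted p = 0.277 with an estimated correlation) and axonemal dyneins in 2 of 9 [5] (camera adjusted p = 0.0016; adjusted p = 0.412 with an estimated correlation). Actin and Arp2/3 genes rose in 1 of 12 [5] (camera adjusted p = 0.0016; adjusted p = 0.277 with an estimated correlation). Chromosome 4 stood higher as a group although its 1 called gene of 75 [0] fell (camera adjusted p = 0.0039; adjusted p = 0.412 with an estimated correlation), and of these 6 groups fry did not pass that one (adjusted p = 0.180). Camera's calls in this label held with any 1 library left out. Members of these 6 groups lost edgeR's calls without chinmo RNAi 1, and those of the mitochondrial genome also without chinmo RNAi 2 or, but for 1, WT 3. In Ci camera called 8 groups, and of these fry passed none (adjusted p from 0.216 to 0.477) and edgeR called 1 gene, ci on chromosome 4 (1 of 75 [1]). Lower were the mitochondrial genome (median -0.63, camera adjusted p = 1.7e-08; adjusted p = 0.205 with an estimated correlation), glutathione S-transferases (median -0.51, camera adjusted p = 2.1e-06; adjusted p = 0.205 with an estimated correlation) and odorant binding proteins (camera adjusted p = 3.1e-05; adjusted p = 0.205 with an estimated correlation). Axonemal dyneins stood higher (0 of 9 [1], camera adjusted p = 0.011; adjusted p = 0.384 with an estimated correlation). Without Ci 1 the transferase median was -0.80. The other 4 calls did not hold with 1 library left out. Camera adjusted p was 0.0075 for vacuolar ATPase genes (0.0598, 0.0831, 0.159 and 0.0946 without WT 1, WT 2, Ci 2 and Ci 3) and 0.0011 for tetraspanins (0.0594 without Ci 2). It was 0.014 for actin and Arp2/3 genes (0.0634 and 0.189 without WT 1 and Ci 2) and 0.046 for chromosome 4 (0.358, 0.0672 and 0.0526 without WT 2, Ci 1 and Ci 3).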
